A study of Mus musculus with 28 samples.

How the data were processed

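The study measured messenger RNA by microarray in resident macrophages washed from the peritoneal cavity of mice without thioglycollate. Per the labels, the cells were cultured overnight in serum-free medium, non-adherent cells such as lymphocytes were washed off, and total RNA was extracted with Trizol, amplified with the WT Expression Kit and labelled with biotin. There were 28 arrays in 7 groups of 4, which the authors describe as biologically independent experiments. The groups were uninjected wild-type mice, uninjected mice lacking ATF7, and C57BL/6 mice injected intravenously with PBS, LPS, PGN, IMQ or BG and sampled 3 weeks later. Groups were taken from the labels. No paired animals, litters or array dates are given in the sources used here, and numbered arrays of different groups were not treated as pairs.

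The values analysed are the deposited processed ones: 1 intensity per probe set and array, on a linear scale, made by the authors in Affymetrix Expression Console with RMA (background correction, quantile normalisation and summary of the probes). The version of that software and the genome build are not given in the sources used here. Median signal was 107 to 115 and the highest signal 13578 to 16646 per array, and no signal was 0 or negative. The log2 was taken here and no further normalisation was done. Raw scans were not analysed here.

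Of 35556 probe sets, 23410 have a gene in the platform table, 21789 of them 1 symbol and 1621 several, and 12146 have none. Symbols were matched to the annotation table by Entrez identifier for 21698 probe sets, which changed 0 symbols. Only probe sets with 1 symbol were tested as genes. The background floor was the 95th percentile of the mean signals of 1210 odorant and vomeronasal receptor probe sets, genes not expected to be transcribed in macrophages, and came to 6.32 on the log2 scale (80.04 in linear signal). Probe sets above the floor in at least 4 of the 28 arrays were kept, 14800 in all. For a gene with several probe sets the one with the highest mean was used, leaving 13512 genes. Among 740 genes with several probe sets, calls in opposite directions by different probe sets occurred for 3 genes in the knockout (Atxn7l1, Hk1 and Sympk), 1 after IMQ (Slc25a36), 28 after BG and 7 in PBS against wild type. Where all 4 arrays of a group were at or under the floor, the fold is a bound computed against the floor, and where only the mean lay under the floor no fold is given.

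Genes were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 28 arrays, and variances were moderated with an intensity trend. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. The comparisons were the knockout against wild type, each ligand against PBS, PBS against wild type, LPS against each other ligand, the difference between the knockout effect and the LPS effect, and an F test for any ligand. For Atf7 an exact permutation test of 4 against 4 arrays was added, whose smallest possible p is 0.0286. The effects of the knockout and of LPS were compared by correlation across genes and by Fisher's exact tests on called genes. Correlations between ligand effects were set beside 100 simulations of unchanged groups against the same controls, and beside fits with the PBS arrays split between the comparisons.

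There were 36 gene lists, covering macrophage identity, immune and metabolic programmes, stress responses, chromatin, other cell types, genes near Atf7 and background. Each was tested with camera at a preset correlation of 0.01, adjusted over all lists and the 5 main comparisons (for PBS against wild type and the direct comparisons, within the comparison). Camera with an estimated correlation and fry were run beside it. Members called over all genes and members called when p-values were adjusted over the list alone were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

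The groups, lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, Atf7, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, up to 4 members with the smallest p from each list called or with at least 3 called members, and fixed genes, of which 13 were tested (Cxcl2, Ccl3, Cxcl9, Cxcl10, Ciita, Tnf, Il1b, Tlr4, Tlr2, Nod1, Nod2, Tlr7 and Clec7a). It also names the 8 genes with the largest change shared by the knockout and LPS. Examples in the text were picked from the genes the rule names, except for members said to be chosen after their values were seen. Predicted genes and members of the odorant, small nucleolar RNA and microRNA lists were not named.

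The procedure was tested on simulated LPS and PBS groups (13512 genes, 200 shifted). It recovered 94.03% of genes shifted by 0.5 (log2) and 100% of those by 1 or 2. It called 206 genes (10 unshifted), the planted list and 0 of 35 unshifted ones. Correlated genes and array shifts were not simulated. With 4 arrays per group, smaller shifts are recovered less often, and an absent call does not show an absent difference. Alternatives covered scaling between arrays, the filter, the probe sets of a gene, the variance model, array weights, the arrays in the fit, the threshold, a replicate block, the B cell markers as a covariate, and leaving out each array. A background covariate, the second Atf7 probe set and a direct comparison of PGN with IMQ were chosen after seeing the data. Probe sets with several symbols or none cannot be assigned to 1 gene and were not tested.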

Results

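Messenger RNA was measured on 28 arrays of peritoneal resident macrophages from mice, in 7 groups of 4 biologically independent arrays. These cells are the long-lived macrophages of the peritoneal cavity. Mice of 2 groups received no injection and were either wild type or lacked ATF7, a stress-responsive transcription factor of the ATF/CREB family. The other 5 groups were wild-type mice sampled 3 weeks after an intravenous injection of PBS, which served as the control, or of 1 of 4 ligands of innate immune receptors. The ligands were lipopolysaccharide (LPS, sensed by TLR4), PGN, imiquimod (IMQ, sensed by TLR7) and β-glucan (BG, sensed by dectin-1, the product of Clec7a). The comparisons asked what the loss of ATF7 changed without injection and what each ligand had left behind after 3 weeks.

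Arrays of 1 group correlated with each other at 0.985 to 0.996 over all probe sets. After genes at background had been set aside, 13512 genes were tested. Levels are given as mean log2 signal ± SD with n = 4 arrays per group. Called genes given with their levels or a fold had all 4 arrays of one group above all 4 of the other (permutation p = 0.0286), apart from Ccr7, Vsig4, Clec10a, Pcna and Bhlhe41 in the knockout and Cxcl1, Csf1, Icam1, Gla and Mrc1 after LPS. For genes given by a log2 change alone this did not always hold. Gene lists were fixed beforehand, whereas members named because at most 5 genes of a list were called in that direction were chosen after their values were seen. They are introduced as exceptions or as the called members. Of 180 list results in the 5 main comparisons camera called 62, and none kept its call when the correlation between genes was estimated (lowest adjusted p = 0.678). No list called in the 5 main comparisons turned its direction when arrays were centred or quantile-normalised again.

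Atf7 was measured by 2 probe sets. The level from probe set 10433032 was 7.08 ± 0.10 in the knockout against 9.97 ± 0.11 in wild type, 7.4-fold lower (limma adjusted p = 1.75e-19, exact permutation p = 0.0286, the smallest possible). Probe set 10433034, which has the higher mean and stands for the gene elsewhere, fell 1.36-fold, from 10.73 ± 0.079 to 10.28 ± 0.042 (adjusted p = 7.7e-08, exact permutation p = 0.0286). The knockout labels therefore matched the arrays, although the sources used here do not say which part of the gene was deleted or where the probes lie relative to it. After BG both probe sets were also lower than after PBS, 9.71 ± 0.086 against 10.04 ± 0.23 (adjusted p = 0.00279) and 10.46 ± 0.066 against 10.71 ± 0.11 (adjusted p = 8.98e-05), with an exact permutation p of 0.0286 for each. After LPS, PGN and IMQ, and in PBS against wild type, neither probe set passed (limma adjusted p from 0.158 to 0.806).

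**Figure D1:**
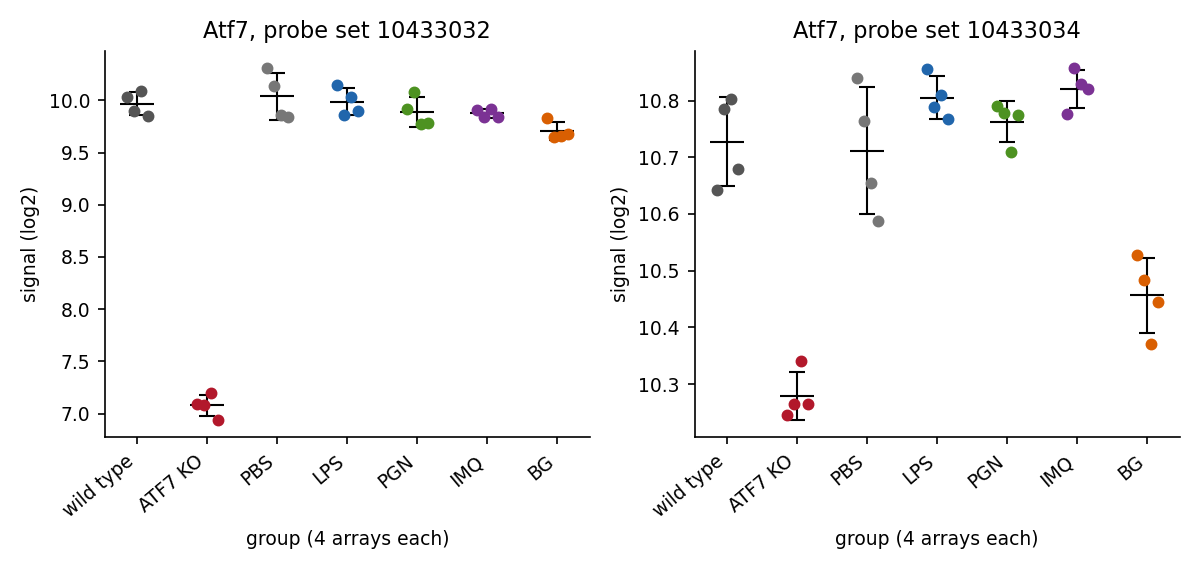
Log2 signal of the 2 Atf7 probe sets on each of the 28 arrays, by group; points are arrays and bars are group means with the SD. The 4 knockout arrays lie between 6.94 and 7.19 for probe set 10433032, against 9.85 to 10.09 in wild type.

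Loss of ATF7 without any injection was accompanied by lower expression of genes that mark large peritoneal macrophages, by fewer transcripts of the cell cycle, and by higher expression of interferon-response genes. Gata6, the transcription factor that maintains the identity of these cells, fell 2.85-fold (8.97 ± 0.23 against 10.48 ± 0.27, limma adjusted p = 8.58e-10). Nt5e, an ecto-nucleotidase, fell 5.18-fold (6.50 ± 0.28 against 8.88 ± 0.45, adjusted p = 2.21e-08). Vcan, a matrix proteoglycan gene, also fell (6.07 ± 0.26 against 8.25 ± 0.73, adjusted p = 9.17e-07), to a mean under the background floor of 6.32. The largest rise among named genes was that of the iron exporter Slc40a1, 5.29-fold (8.79 ± 0.49 against 6.39 ± 0.40, adjusted p = 9.89e-07). In all, 3830 of 13512 genes changed (28.3%), 2388 higher and 1442 lower, and 417 of them by at least 1.5-fold. With each array centred on its median the split became 3404 higher and 958 lower.

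Of 28 measured identity genes of large peritoneal macrophages, 15 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 1.49e-07, and 0.678 with an estimated correlation). Thbs1, encoding thrombospondin, fell 2.15-fold (12.09 ± 0.32 against 13.19 ± 0.12, adjusted p = 1.41e-08), and Alox15, a lipoxygenase typical of these cells, fell 1.95-fold (adjusted p = 4.57e-08). The exceptions were Cd5l, a secreted scavenger protein, 2.59-fold higher (3.73e-07), and the complement receptor gene Vsig4, 1.61-fold higher (0.00102). Markers of monocyte-derived peritoneal macrophages and dendritic cells also moved down, 7 of 19 against 2 up (9 and 2 adjusted over the list alone; camera adjusted p = 0.0259, and 0.678 with an estimated correlation). Among them Napsa fell 1.87-fold, Cd209a 1.79-fold and the chemokine receptor gene Ccr7 1.89-fold, although the change of Ccr7 turned to 0.098 with the B cell markers as a covariate (adjusted p = 0.827). Folr2, a folate receptor gene, rose 2.84-fold (10.03 ± 0.30 against 8.52 ± 0.34, adjusted p = 1.42e-07) and the lectin gene Clec10a rose 1.27-fold (0.04) as the exceptions. The calls of Clec10a and this last list ended without wild-type replicate 1, 2 or 3 or knockout replicate 1 or 2 (adjusted p from 0.052 to 0.204, each for at least 1 of these arrays). In the same arrays the mean level of 22 B cell markers was 7.64 ± 0.20 against 8.31 ± 0.25.

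Interferon-response genes were higher in the knockout almost without exception. Of 41 measured type I interferon-response genes, 39 rose (41 adjusted over the list alone; median rise 0.92 on the log2 scale; camera adjusted p = 2.86e-23, and 0.678 with an estimated correlation). The antiviral genes Oas3, Ifit2 and Ifit3 rose 3.23-fold (10.20 ± 0.57 against 8.51 ± 0.48, adjusted p = 6.81e-06), 3.17-fold (9.48 ± 0.69 against 7.82 ± 0.40, 0.000207) and 2.93-fold. Oas1a rose 2.18-fold (1.71e-07) and Bst2, which tethers virions to the membrane, 2.13-fold. Among 17 GTPases and chemokines induced by interferon-γ, 11 rose (12 adjusted over the list alone; camera adjusted p = 2.46e-05, and 0.684 with an estimated correlation). Iigp1 was 2.88-fold, the Fc receptor gene Fcgr1 2.23-fold and Irgm1 1.8-fold higher. Genes of MHC class I presentation followed, 15 of 17 being higher (15 adjusted over the list alone; camera adjusted p = 2.07e-10, and 0.678 with an estimated correlation). They included the immunoproteasome subunit Psmb8 (1.79-fold, 9.69 ± 0.26 against 8.85 ± 0.18, 2.36e-06), the proteasome activator Psme2 (1.57-fold) and the peptide transporter Tap2 (1.43-fold).

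Genes of inflammatory cytokines moved mostly upward. Of 39 cytokine and chemokine genes induced through NF-κB, 16 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.00164, and 0.773 with an estimated correlation). Tnf rose 1.86-fold (10.68 ± 0.15 against 9.79 ± 0.20, adjusted p = 3.09e-06), Il1a 1.74-fold and Ccl4 1.65-fold. By contrast Il1b, which encodes another pyrogenic cytokine, fell 1.77-fold (7.43 ± 0.35 against 8.26 ± 0.14, adjusted p = 0.000435), as did Nlrp3, the inflammasome sensor gene, by 0.30 on the log2 scale (0.000236). The chemokine gene Ccl3 rose 1.22-fold (limma adjusted p = 0.00107). Among genes chosen beforehand, which included chemokine and cytokine genes, Ciita and the receptors of the ligands, 13 were tested. Cxcl2 (adjusted p = 0.0548), Cxcl10 (0.0593), Cxcl9 (0.264), Ciita (0.406), Tlr4 (0.837), Tlr2 (0.443), Nod1 (0.13), Nod2 (0.645), Tlr7 (0.0563) and Clec7a (0.188) did not pass. Without 1 array at a time some of these passed, namely Tlr7 without wild-type replicate 1 (adjusted p = 0.00435) or knockout replicate 3 (0.0369), Cxcl2 without wild-type replicate 4 (0.0269), Cxcl10 without wild-type replicate 4 (0.0446) or knockout replicate 1 (0.042), Nod1 without knockout replicate 1 (0.0472) and Clec7a without knockout replicate 4 (0.0134). Pattern recognition receptors and their adaptors went both ways, 8 of 43 up and 5 down (8 and 5 adjusted over the list alone; camera adjusted p = 0.474). The mannose receptor gene Mrc1 rose 2.62-fold (8.49 ± 0.16 against 7.10 ± 0.15, adjusted p = 1.28e-07) and Tlr1 rose 1.89-fold (1.03e-07). The called members that fell were Naip5, Clec4d, Clec4a2, Pglyrp1 and Tlr8, by 0.43, 0.16, 0.55, 0.30 and 0.23 on the log2 scale. Without wild-type replicate 1 or 3 or knockout replicate 2 or 4, the calls of Pglyrp1 and Tlr8 ended (adjusted p from 0.0529 to 0.0855, each for at least 1 of these arrays).

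Receptors that bind apoptotic cells or scavenged ligands included several of the larger rises, although 13 of 31 such genes rose and 6 fell (14 and 7 adjusted over the list alone; camera adjusted p = 0.363). Siglec1, a sialic acid-binding lectin gene, rose 2.81-fold (10.48 ± 0.44 against 8.99 ± 0.36, adjusted p = 1.49e-06), Axl, a receptor for phosphatidylserine-bound ligands, 2.52-fold (11.30 ± 0.20 against 9.96 ± 0.28, 1.31e-08), and its ligand Gas6 2-fold. Among 21 genes of alternative activation, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.103). The haemoglobin scavenger receptor gene Cd163, at background in every wild-type array, was at least 2.25-fold higher (7.49e-09), and Pparg, a lipid-sensing nuclear receptor gene, rose 1.73-fold, while Pdcd1lg2, at background in every knockout array, fell (0.0263) as the exception. Pdcd1lg2 lost its call without wild-type replicate 4 or knockout replicate 1 (adjusted p from 0.107 to 0.129).

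In the knockout more genes rose than fell in the lists of antioxidant defence, oxidative phosphorylation, cholesterol synthesis, ATF4 targets and lysosomes. Of 23 antioxidant genes under NRF2, 17 rose (19 adjusted over the list alone; camera adjusted p = 4.86e-07, and 0.678 with an estimated correlation). Among them were the malic enzyme gene Me1 (1.65-fold, adjusted p = 1.36e-06) and the autophagy adaptor gene Sqstm1 (1.33-fold). Of 38 genes of oxidative phosphorylation, 25 rose (27 adjusted over the list alone; camera adjusted p = 1.3e-06, and 0.678 with an estimated correlation), by amounts such as 1.25-fold for Ndufa9 (0.000135) and 1.2-fold for Uqcrc1. Cholesterol synthesis genes rose in 10 of 20 cases (12 adjusted over the list alone; camera adjusted p = 0.000496, and 0.744 with an estimated correlation). Cyp51 was 1.54-fold (0.0018) and Hsd17b7 1.5-fold (0.000519) higher. In the list of ATF4 targets and the unfolded protein response, 13 of 30 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.00227, and 0.678 with an estimated correlation). The asparagine synthetase gene Asns rose 2.02-fold (9.41 ± 0.25 against 8.40 ± 0.14, adjusted p = 4.07e-08), and the exceptions Ddit4, Ern1 and Phgdh fell by 0.49, 0.21 and 0.35 on the log2 scale (Phgdh turned to 0.011 with the B cell markers as a covariate). Lysosome and autophagy genes rose in 20 of 33 cases and fell in 5 (21 and 5 adjusted over the list alone; camera adjusted p = 6.76e-05, and 0.678 with an estimated correlation). The lysosomal glucosidase gene Gaa rose 1.44-fold (adjusted p = 7.34e-08) and Npc2, a lysosomal cholesterol carrier gene, 1.31-fold. The called members that fell, Wipi1, Map1lc3a, Uvrag, Ulk1 and Atg7, all act in autophagosome formation and dropped by 0.36, 0.31, 0.21, 0.30 and 0.16 on the log2 scale. Leaving out wild-type replicate 1, 2 or 4 or knockout replicate 1, 2, 3 or 4 ended the calls of Ern1, Phgdh and Atg7 (adjusted p from 0.0525 to 0.147, each for at least 1 of these arrays).

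Cell cycle genes were lower in the knockout, 38 of 53 having fallen, with a median change of -0.52 (42 adjusted over the list alone; camera adjusted p = 2.2e-19, and 0.678 with an estimated correlation). The cyclin genes Ccna2 and Ccnb2 fell 2.83-fold (6.33 ± 0.38 against 7.83 ± 0.40, adjusted p = 2.59e-06) and 2.73-fold (7.22 ± 0.31 against 8.66 ± 0.27, 5.6e-07), and the replication clamp gene Pcna, 1.18-fold higher (0.00851), was the exception. Ribosomal protein genes fell in 43 of 57 cases (45 adjusted over the list alone; camera adjusted p = 1.21e-19, and 0.678 with an estimated correlation). Rps28 was 1.37-fold (adjusted p = 1e-06) and Rpl13 1.29-fold lower. The 2 exceptions in that list, Rps19bp1 and Rps27l (0.23 and 0.23 on the log2 scale), include a gene for a binding partner rather than a ribosomal protein. Markers of B cells, the main lymphocytes of the peritoneal cavity, fell in 17 of 22 cases (18 adjusted over the list alone; median -0.75; camera adjusted p = 5.75e-12, and 0.678 with an estimated correlation). Examples were Cd79b (2.22-fold, 9.47 ± 0.40 against 10.62 ± 0.33, 2.84e-06) and the transcription factor gene Ebf1 (2.4-fold). Bhlhe41 was the exception (1.69-fold higher, 0.000471). Of 3 eosinophil markers 2 fell, not separated from B cells (2 adjusted over the list alone; camera adjusted p = 0.00413, and 0.678 with an estimated correlation). Cd24a and Il5ra fell 2.66-fold (7.34e-08) and 2.27-fold (5.95e-05), but Siglecf did not pass (0.354). The calls of Pcna and Rps27l ended without knockout replicate 1 or 2 or wild-type replicate 1 or 2 (adjusted p from 0.0561 to 0.189, each for at least 1 of these arrays).

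Lists included as measures of RNA recovery and background moved as well. Small nucleolar RNAs fell in 13 of 41 cases and rose in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00296, and 0.758 with an estimated correlation). MicroRNA probe sets went 7 up and 7 down of 115 (4 and 3 adjusted over the list alone; camera adjusted p = 0.0183, and 0.812 with an estimated correlation), and odorant and vomeronasal receptor genes fell in 6 of 110 cases (1 adjusted over the list alone; camera adjusted p = 0.000167, and 0.773 with an estimated correlation). The call for microRNA probe sets ended without wild-type replicate 2 (adjusted p = 0.31) and without knockout replicate 2 (0.0715) or 3 (0.0581). With the mean of the B cell markers as a covariate, 1423 of the 13512 genes passed instead of 3830.

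**Figure D2:**
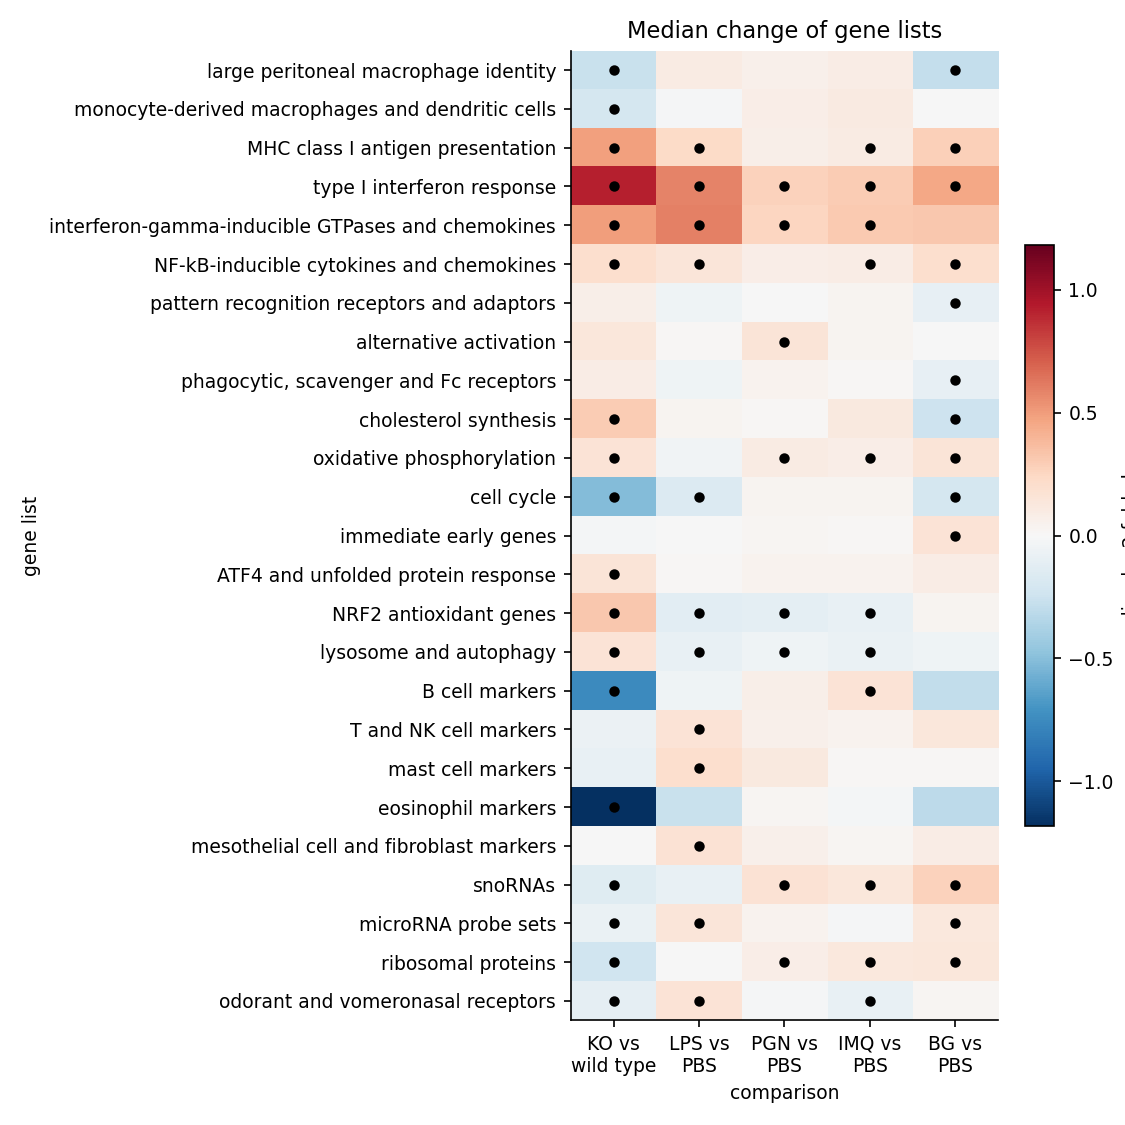
Median log2 fold change of the tested members of 25 gene lists (vertical axis) in the 5 main comparisons (horizontal axis), coloured from blue (lower) to red (higher), with a dot where camera called the list at an adjusted p under 0.05. Type I interferon-response genes have a median of 0.92 in the knockout, 0.59 after LPS and 0.46 after BG.

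After LPS, 3 weeks after the injection, macrophages held more transcripts of interferon-inducible genes than after PBS. Cxcl10, a chemokine that attracts activated T cells, rose 3.31-fold (10.85 ± 0.60 against 9.12 ± 0.75, limma adjusted p = 0.0128) and the related Cxcl9 rose 2.77-fold (9.57 ± 0.32 against 8.10 ± 0.24, 0.014). Of 41 type I interferon-response genes, 32 rose (38 adjusted over the list alone; median rise 0.59; camera adjusted p = 4.06e-22, and 0.678 with an estimated correlation). Ifit3 was 2.44-fold (10.15 ± 0.46 against 8.86 ± 0.36, 0.0128), Rtp4 1.7-fold and Oasl2 1.69-fold higher. Of 17 interferon-γ-induced GTPases and chemokines, 13 rose (16 adjusted over the list alone; camera adjusted p = 1.18e-10, and 0.678 with an estimated correlation). Among them were Iigp1 (2.58-fold, 8.40 ± 0.16 against 7.03 ± 0.56, 0.0179), Gbp9 (1.87-fold) and the transcription factor gene Batf2 (1.36-fold, 0.0128). The inducible nitric oxide synthase gene Nos2 rose 2.42-fold (8.11 ± 0.39 against 6.84 ± 0.51, 0.0201). In the same arrays the mean of 110 odorant and vomeronasal receptor genes, which serve as background, was 6.66 ± 0.087 against 6.50 ± 0.025. Without LPS replicate 2 none of these gene calls held (adjusted p from 0.0603 for Batf2 to 0.0881 for Nos2), and those of Iigp1, Gbp9 and Nos2 also ended without PBS replicate 3 (0.0618, 0.0514 and 0.07). Of the 32 type I interferon genes, 0 stayed called without LPS replicate 2, 8 without PBS replicate 3 and 21 without PBS replicate 4 or LPS replicate 3. Without that array camera still called the list (adjusted p = 8.12e-25), its mean change lying 0.62 above that of the other genes.

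In all, 1335 of 13512 genes changed after LPS (9.88%), 589 higher and 746 lower, and 63 of them by at least 1.5-fold. The count fell to 4 without LPS replicate 2, to 172 without PBS replicate 3, to 440 without PBS replicate 4, to 596 without LPS replicate 1 and to 849 without PBS replicate 2. The 4 genes left without LPS replicate 2 were Abhd12, Kif3a and Pam16, which fell by 0.27, 0.47 and 0.27 on the log2 scale, and Trafd1, higher by 0.32 (adjusted p = 0.0453 for each). The split was 385 higher and 1219 lower with centred arrays, and 423 and 440 after quantile normalisation. With the mean odorant and vomeronasal receptor signal as a covariate, chosen after seeing the data, 12 genes passed. The median change of the type I interferon genes was then 0.56, against 0.59 without it.

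MHC class I presentation genes rose in 8 of 17 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 6.77e-05, and 0.678 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, rose 1.28-fold (limma adjusted p = 0.0137) and Tap2 1.25-fold (0.0128), and the chaperone gene Pdia3, which fell by 0.26 on the log2 scale, was the exception. Of 39 NF-κB-induced cytokine and chemokine genes 5 rose (10 adjusted over the list alone; camera adjusted p = 3.6e-05, and 0.723 with an estimated correlation). The called members were Slc7a2, a transporter of arginine (1.57-fold, 0.0178), Cxcl1 (1.28-fold), Csf1 (1.21-fold), Ccl5 (1.32-fold) and Icam1 (1.28-fold). Tnf (log2 difference 0.35, adjusted p = 0.0622), Ccl3 (0.156), Cxcl2 (0.368), Il1b (0.83) and Ciita (0.485) did not pass. The LPS receptor gene Tlr4 (0.146) and Tlr2 (0.53), Nod1 (0.12), Nod2 (0.154) and Clec7a (0.207) did not pass either, while Tlr7 fell 1.14-fold (10.91 ± 0.034 against 11.10 ± 0.033, 0.0324). Without LPS replicate 1, 2, 3 or 4 or PBS replicate 1, 2, 3 or 4, the calls of Nlrc5, Tap2, Pdia3, Slc7a2, Cxcl1, Csf1, Ccl5, Icam1 and Tlr7 ended (adjusted p from 0.0504 to 0.171, each for at least 1 of these arrays and for every gene among them without LPS replicate 2). Tnf passed without PBS replicate 2 (0.0485) or LPS replicate 4 (0.0487).

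Lower after LPS were some genes of antioxidant defence, lysosomes and the cell cycle. The called members among 23 NRF2 genes were Prdx1, Gsta3 and Gclm, which fell by 0.23, 0.71 and 0.30 on the log2 scale (4 adjusted over the list alone; camera adjusted p = 0.00109, and 0.773 with an estimated correlation). Among 33 lysosome and autophagy genes 6 fell (6 adjusted over the list alone; camera adjusted p = 0.000231, and 0.684 with an estimated correlation). They included the proton pump gene Atp6v1a (1.14-fold) and the galactosidase gene Gla (1.26-fold). Smc2 and Cdca8 were the called members of 53 cell cycle genes and fell by 0.38 and 0.29 (2 adjusted over the list alone; camera adjusted p = 0.00102, and 0.812 with an estimated correlation). Larger falls of single genes included Hpgd, which degrades prostaglandins (1.91-fold, 7.61 ± 0.31 against 8.54 ± 0.31, 0.0179) and Ms4a4a (1.7-fold), and the mannose receptor gene Mrc1 fell 1.51-fold (0.0227). Hpgd and Mrc1 were also higher after PBS than in uninjected wild type. Prdx1, Gsta3, Gclm, Atp6v1a, Gla, Smc2, Cdca8, Hpgd, Ms4a4a, Mrc1 and the cell cycle list lost their calls without PBS replicate 2, 3 or 4 or LPS replicate 1, 2 or 3 (adjusted p from 0.0517 to 0.161, each for at least 1 of these arrays and for every gene among them without LPS replicate 2).

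Markers of other cells and background also moved after LPS. The medians of the lists named here had the opposite sign in PBS against wild type. For odorant and vomeronasal receptor genes they were 0.163 after LPS and -0.188 in PBS against wild type. The called mesothelial and fibroblast markers were Col1a1, Msln and Bgn, 3 of 17, with rises of 0.25 and 0.23 on the log2 scale and, from background, of at least 1.09-fold (6 adjusted over the list alone; camera adjusted p = 4.8e-05, and 0.678 with an estimated correlation). The called mast cell markers were Slc18a2 and Hdc, 2 of 5 (at least 1.13-fold from background and 0.41 on the log2 scale; 4 adjusted over the list alone; camera adjusted p = 0.0175, and 0.678 with an estimated correlation). Of 9 T and NK cell markers Cd247 and Tbx21 rose from mean levels under the background floor (Cd247 at least 1.06-fold) and Cd28 fell 1.75-fold (3 and 1 adjusted over the list alone; camera adjusted p = 0.0259, and 0.678 with an estimated correlation). Odorant and vomeronasal receptor genes rose in 18 of 110 cases (20 adjusted over the list alone; camera adjusted p = 2.15e-11, and 0.678 with an estimated correlation) and microRNA probe sets in 16 of 115 (23 adjusted over the list alone; camera adjusted p = 3.47e-10, and 0.678 with an estimated correlation). Leaving out PBS replicate 1, 2, 3 or 4 or LPS replicate 1, 2, 3 or 4 ended the calls of Col1a1, Msln, Bgn, Slc18a2, Hdc, Cd247, Tbx21, Cd28 and the T and NK cell list (adjusted p from 0.0508 to 0.218, each for at least 1 of these arrays and for every gene among them without LPS replicate 2).

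Whether macrophages that lack ATF7 resemble those that had met LPS was asked across genes. Type I interferon-response genes rose in both states, 39 of 41 in the knockout and 32 after LPS, with 30 in both. Across these 41 genes the 2 sets of log2 changes correlated (Pearson's r = 0.678, Spearman's rho = 0.73, permutation p = 1e-05, the smallest possible with 100000 resamples, and r = 0.651 without the 2 farthest genes). Genes are not independent replicates of each other. The 8 genes with the largest change shared by both were Iigp1, Ifit2, Ifit3, Ifit1, Tnfsf10, Rsad2, Slfn1 and Ifit3b, all higher, and Iigp1 rose 2.88-fold in the knockout and 2.58-fold after LPS. Across all 13512 genes, however, Pearson's r was 0.0166 and Spearman's rho -0.181, and without the interferon lists r was -0.0589 over 13454 genes. Over the 416 genes called in both, a selected set, r was 0.505 and rho 0.315. Genes higher in both states numbered 102 where 104.1 were expected for independent lists (Fisher's exact p = 0.868). Another 88 were lower in both where 79.61 were expected (Fisher's exact p = 0.3). By contrast, 186 genes were higher in the knockout and lower after LPS where 131.8 were expected (Fisher's exact p = 3.25e-07), and 40 were lower in the knockout and higher after LPS where 62.86 were expected (p = 0.0013). These overlaps and the 30 interferon genes rest on the LPS calls, of which 4 were left without LPS replicate 2 and 12 with the background covariate, none of them among the 32 interferon genes. A test of the difference between the 2 effects called 3958 genes, 2542 with the larger value in the knockout and 1416 with the larger value after LPS (4029 and 680 with centred arrays). It called 1531 with the background covariate and 1912 with the B cell markers as a covariate. In that test 15 of 28 macrophage identity genes had the lower value in the knockout (16 adjusted over the list alone; camera adjusted p = 1.6e-07, and 0.279 with an estimated correlation).

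**Figure D3:**
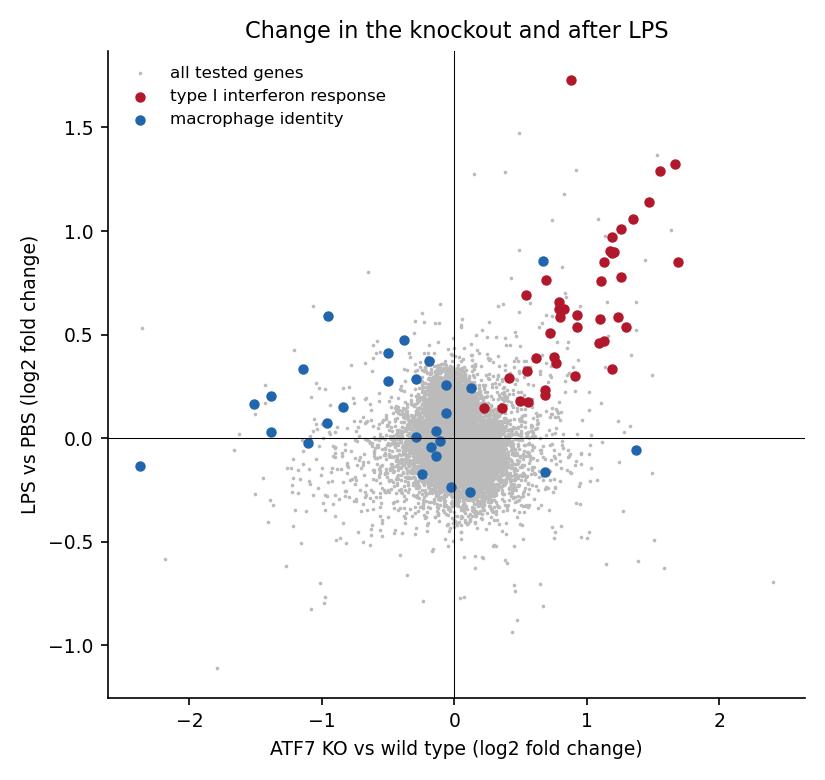
Log2 fold change after LPS against PBS (vertical axis) and in the ATF7 knockout against wild type (horizontal axis) for each of the 13512 tested genes (grey), with the 41 type I interferon-response genes in red and 28 identity genes of large peritoneal macrophages in blue. Pearson's r is 0.0166 over all genes and 0.678 over the interferon genes.

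Differences from PBS were also called 3 weeks after the injection of PGN. Vegfa, the angiogenic growth factor gene, rose 1.76-fold (8.74 ± 0.15 against 7.92 ± 0.15, limma adjusted p = 5.4e-06), Tgm2, a transglutaminase of alternatively activated macrophages, 1.59-fold (9.89 ± 0.10 against 9.22 ± 0.14, 5.35e-05), and Hp, encoding haptoglobin, 1.58-fold (11.74 ± 0.049 against 11.08 ± 0.29, 0.000179). Ms4a4a fell 1.89-fold (0.00434), Clec4n, a receptor for fungal mannans, 1.84-fold (9.76 ± 0.074 against 10.63 ± 0.41, 0.00601), and the arginase gene Arg2 1.57-fold (10.10 ± 0.15 against 10.75 ± 0.059, 0.000493). In all, 528 of 13512 genes changed (3.91%), 283 higher and 245 lower, and 21 by at least 1.5-fold. The count fell to between 283 and 341 without PGN replicate 4 (283), 3 (311) or 1 (341) or without PBS replicate 3 (336) or 4 (340).

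Among 21 alternative activation genes the called members were Tgm2 and Ppargc1b, a coactivator of mitochondrial genes (1.27-fold, 0.0149), which rose (3 adjusted over the list alone; camera adjusted p = 0.0399, and 0.678 with an estimated correlation). Genes of oxidative phosphorylation rose in 7 of 38 cases (14 adjusted over the list alone; camera adjusted p = 8.14e-05, and 0.737 with an estimated correlation). Examples were Ndufb9 (1.28-fold, 0.000367) and Cox6c (1.22-fold, 0.000134). Ribosomal protein genes rose in 10 of 57 cases (17 adjusted over the list alone; camera adjusted p = 2.55e-05, and 0.744 with an estimated correlation). Examples were Rps18 (1.23-fold, 0.00215) and Rpl26 (1.21-fold). The exception was Rpl7l1 (fell by 0.16). Small nucleolar RNAs rose in 12 of 41 cases (17 adjusted over the list alone; camera adjusted p = 4.51e-07, and 0.678 with an estimated correlation). Among 23 NRF2 genes the called members Gstm1 and Hmox1 fell by 0.34 and 0.37, and Slc40a1 fell to a mean under the background floor (5 adjusted over the list alone; camera adjusted p = 0.000231, and 0.737 with an estimated correlation). Among 33 lysosome and autophagy genes the called member Atp6v1a fell 1.23-fold (4 down and 2 up adjusted over the list alone; camera adjusted p = 0.0159, and 0.811 with an estimated correlation). The calls of Ppargc1b, Rpl7l1, Gstm1, Hmox1, Slc40a1, the alternative activation list and the lysosome list ended without PBS replicate 1, 2, 3 or 4 or PGN replicate 1, 2, 3 or 4 (adjusted p from 0.0507 to 0.201, each for at least 1 of these arrays).

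Interferon-response genes had a higher median after PGN, 0.27 over 41 genes (camera adjusted p = 7.02e-06, and 0.812 with an estimated correlation), but 0 of them passed limma's test (0 adjusted over the list alone, 11 higher at an unadjusted p under 0.05). The same held for 17 interferon-γ-induced GTPases and chemokines, with a median of 0.25, 0 passing in limma (1 adjusted over the list alone, 5 higher and 1 lower at an unadjusted p under 0.05) and camera adjusted p = 0.0292, and 0.812 with an estimated correlation. Fry, which asks only whether the genes of a list move one way, gave adjusted p = 0.247 and 0.33. Of the NF-κB-induced genes Nlrp3 rose by 0.47 on the log2 scale (adjusted p = 4.24e-05) and Ccl3 1.2-fold (0.0201), 2 of 39 (2 adjusted over the list alone; camera adjusted p = 0.078). Of the pattern recognition genes the cytosolic receptor gene Nod1 rose 1.28-fold (8.91 ± 0.072 against 8.56 ± 0.21, 0.0145), while Clec4n, Clec4d (1.15-fold, 0.00317) and the adaptor gene Tirap (1.19-fold, 0.00285) fell, 1 up and 3 down of 43 (1 and 4 adjusted over the list alone; camera adjusted p = 0.229). The other genes chosen beforehand did not pass (adjusted p from 0.203 for Cxcl10 to 0.919 for Nod2). Without PBS replicate 1, 3 or 4 or PGN replicate 1, 2 or 4, the calls of Ccl3, Nod1 and the interferon-γ list ended (adjusted p from 0.0505 to 0.445, each for at least 1 of these arrays).

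After IMQ the genes with the largest changes included those named for PGN. Tgm2 rose 1.71-fold (9.99 ± 0.085 against 9.22 ± 0.14, limma adjusted p = 5.31e-06), Vegfa 1.68-fold (8.67 ± 0.062 against 7.92 ± 0.15, 5.31e-06) and Hp 1.67-fold (11.82 ± 0.072 against 11.08 ± 0.29, 2.55e-05). Slc40a1, the iron exporter gene, was at background in every IMQ array and at least 2.03-fold lower (0.00212), Clec4n fell 2.32-fold (9.42 ± 0.13 against 10.63 ± 0.41, 0.000191) and Arg2 1.69-fold (4.9e-05). In all, 769 of 13512 genes changed (5.69%), 418 higher and 351 lower (433 and 585 after quantile normalisation), and 28 by at least 1.5-fold. The count fell to 400 without IMQ replicate 1, 424 without PBS replicate 4, 449 without IMQ replicate 3, 474 without PBS replicate 3 and 479 without IMQ replicate 2. A direct comparison of PGN with IMQ, chosen after seeing the data, called 0 genes by limma, with 669 at an unadjusted p under 0.05.

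Ribosomal protein genes rose in 21 of 57 cases after IMQ (28 adjusted over the list alone; camera adjusted p = 8.75e-12, and 0.678 with an estimated correlation). Rps3a1 was 1.36-fold, Rps18 1.25-fold (0.000882) and Rpl5 1.22-fold (0.000731) higher. The called members of 38 oxidative phosphorylation genes were Ndufb9, Cox6c, Ndufv2, Ndufa1 and Ndufs4, which rose by 0.37, 0.25, 0.27, 0.33 and 0.23 on the log2 scale (10 adjusted over the list alone; camera adjusted p = 0.00281, and 0.812 with an estimated correlation). Small nucleolar RNAs rose in 13 of 41 cases (19 adjusted over the list alone; camera adjusted p = 9.08e-07, and 0.678 with an estimated correlation). NRF2 genes fell in 6 of 23 cases (8 adjusted over the list alone; camera adjusted p = 8.12e-05, and 0.725 with an estimated correlation). Among them were the glutathione transferase gene Gstm1 (1.4-fold, 0.000655) and the haem oxygenase gene Hmox1 (1.35-fold, 0.0055). The called lysosome and autophagy genes Atp6v1a, Map1lc3a, Ctsd, Gpnmb and Mcoln1, 5 of 33, fell by 0.36, 0.37, 0.20, 0.59 and 0.17 (10 adjusted over the list alone; camera adjusted p = 2.94e-05, and 0.678 with an estimated correlation). Odorant and vomeronasal receptor genes had a median of -0.086 with 0 of 110 called by limma (0 adjusted over the list alone, 17 lower at an unadjusted p under 0.05; camera adjusted p = 5.89e-06, and 0.737 with an estimated correlation). Ndufs4, Mcoln1 and the oxidative phosphorylation list lost their calls without PBS replicate 1, 3 or 4 or IMQ replicate 1, 2, 3 or 4 (adjusted p from 0.052 to 0.152, each for at least 1 of these arrays).

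Few genes of the immune lists passed after IMQ. The called type I interferon gene was Phf11d, 1.56-fold higher (0.0397), and the median over 41 genes was 0.30 (0 adjusted over the list alone, 16 higher at an unadjusted p under 0.05; camera adjusted p = 6.03e-07, and 0.773 with an estimated correlation). Interferon-γ-induced GTPases and chemokines had a median of 0.31 with 0 of 17 called by limma (3 adjusted over the list alone, 9 higher at an unadjusted p under 0.05; camera adjusted p = 0.000737, and 0.75 with an estimated correlation). Psmb10, 1.28-fold higher, was the called MHC class I gene of 17 (1 adjusted over the list alone; camera adjusted p = 0.0459, and 0.812 with an estimated correlation). Nlrp3, 1.44-fold higher (9.31 ± 0.086 against 8.79 ± 0.041, adjusted p = 3.57e-06), was the called gene of 39 induced by NF-κB (1 adjusted over the list alone; camera adjusted p = 0.0451, and 0.835 with an estimated correlation). The B cell markers Cd22 and Bank1 rose 1.39-fold and 1.37-fold, 2 of 22 (2 adjusted over the list alone; camera adjusted p = 0.0179, and 0.812 with an estimated correlation). Of the genes chosen beforehand Nod1 rose 1.28-fold (0.00987), and Tlr7, whose product senses IMQ, had an adjusted p of 0.686. The others did not pass either (limma adjusted p from 0.155 for Cxcl10 to 0.974 for Clec7a). Leaving out PBS replicate 1, 3 or 4 or IMQ replicate 1, 2, 3 or 4 ended the calls of Phf11d, Psmb10, Cd22, Bank1, Nod1, the MHC class I list, the NF-κB list and the B cell list (adjusted p from 0.0503 to 0.585, each for at least 1 of these arrays).

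BG left the largest number of differences among the ligands, with lower expression of macrophage identity genes and of receptors and higher expression of chemokines. Thbs1 fell 4.02-fold (10.92 ± 0.075 against 12.93 ± 0.11, limma adjusted p = 7.68e-14), Vcan 3.26-fold (6.49 ± 0.28 against 8.19 ± 0.49, 1.4e-05), Nt5e 3.2-fold (6.92 ± 0.36 against 8.59 ± 0.52, 1.9e-06) and Arg2 2.57-fold (9.39 ± 0.098 against 10.75 ± 0.059, 2.32e-10). The calcium-binding protein gene S100a6 rose 2.72-fold (9.83 ± 0.089 against 8.38 ± 0.53, 1.8e-06) and Ccl2, the main monocyte chemoattractant gene, 2.67-fold (10.66 ± 0.15 against 9.24 ± 0.40, 2.93e-06). In all, 5624 of 13512 genes changed (41.6%), 2729 higher and 2895 lower, of which 312 by at least 1.5-fold.

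Of 28 identity genes of large peritoneal macrophages, 17 fell and 2 rose (17 and 3 adjusted over the list alone; camera adjusted p = 7.17e-05, and 0.678 with an estimated correlation). Gata6 fell 1.91-fold (9.41 ± 0.13 against 10.35 ± 0.23, adjusted p = 7.84e-07), the coagulation factor gene F5 2.53-fold (1.75e-06) and Vsig4 2.47-fold (1.86e-07). The exceptions were Cd5l and Cd9 (0.47 and 0.26 on the log2 scale). Pattern recognition genes fell in 16 of 43 cases (16 adjusted over the list alone; camera adjusted p = 0.0126, and 0.737 with an estimated correlation). They included Tlr8 (1.62-fold, 10.51 ± 0.11 against 11.21 ± 0.09, 1.66e-08), Ly96, the TLR4 cofactor gene (1.42-fold), and Clec7a, the β-glucan receptor gene (1.23-fold, 10.22 ± 0.068 against 10.53 ± 0.079, 0.00828). The exceptions Tollip, Syk, Nod1 and Marco rose by 0.27, 0.20, 0.25 and 0.42, and Tlr4 (0.237), Tlr2 (0.105), Nod2 (0.14) and Ciita (0.13) did not pass. Phagocytic, scavenger and Fc receptor genes fell in 13 of 31 cases (13 adjusted over the list alone; camera adjusted p = 0.0381, and 0.678 with an estimated correlation). Examples were the oxidised lipoprotein receptor gene Olr1 (2.4-fold, 1.17e-06) and Fcgr3 (1.47-fold). The exceptions were Adgrb1 and Scarf1 (0.33 and 0.32). The calls of Cd5l, Cd9, Nod1, Marco and the phagocytic receptor list ended without PBS replicate 1, 2, 3 or 4 or BG replicate 1, 2, 3 or 4 (adjusted p from 0.0523 to 0.175, each for at least 1 of these arrays). Nod2 passed without PBS replicate 1 (0.0483). In the same arrays the mean of the B cell markers was 8.08 ± 0.046 against 8.33 ± 0.14.

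Interferon and cytokine genes rose after BG. Of 41 type I interferon-response genes, 23 rose (27 up and 1 down adjusted over the list alone; median 0.46; camera adjusted p = 8.52e-05, and 0.812 with an estimated correlation). Cxcl10 was 2.39-fold (10.38 ± 0.44 against 9.12 ± 0.75, adjusted p = 0.00523), Oas3 2.17-fold (0.000558) and Zbp1 1.7-fold higher. Of the genes chosen beforehand, Cxcl9 rose 1.72-fold (8.89 ± 0.36 against 8.10 ± 0.24, 0.045) and Tlr7 fell 1.19-fold (0.000607). MHC class I presentation genes rose in 9 of 17 cases (9 adjusted over the list alone; camera adjusted p = 0.00615, and 0.773 with an estimated correlation). Among them were Psmb8 (1.7-fold, 9.79 ± 0.20 against 9.02 ± 0.075, 4.16e-06) and Tap2 (1.44-fold). The exception was B2m (fell by 0.093). NF-κB-induced genes rose in 18 of 39 cases and fell in 3 (20 and 3 adjusted over the list alone; camera adjusted p = 0.00902, and 0.812 with an estimated correlation). Ccl2, Cxcl2 (1.75-fold, 9.8e-05), Ccl7 (1.72-fold) and Tnf (1.48-fold, 0.000497) rose, and the exceptions Il1b (2.23-fold, 6.73 ± 0.13 against 7.89 ± 0.20, 4.24e-06), Nlrp3 and Plek fell, the last 2 by 0.33 and 0.23 on the log2 scale. Ccl3 rose 1.31-fold (3.22e-05). Immediate early genes rose in 10 of 28 cases and fell in 5 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0451, and 0.678 with an estimated correlation). Hspa1a was 1.63-fold and Dusp5 1.41-fold higher, and Zfp36, Nr4a2, Fosl2, Btg2 and Klf10 were lower by 0.39, 0.51, 0.30, 0.16 and 0.20. Without PBS replicate 1, 2, 3 or 4 or BG replicate 1, 2, 3 or 4, the calls of Cxcl9, B2m, Klf10, the NF-κB list and the immediate early list ended (adjusted p from 0.0504 to 0.146, each for at least 1 of these arrays).

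Metabolic and translation genes moved both ways after BG. Of 38 oxidative phosphorylation genes 22 rose and 3 fell (22 and 3 adjusted over the list alone; camera adjusted p = 0.000167, and 0.744 with an estimated correlation). Ndufa1 was 1.68-fold higher (adjusted p = 3.91e-08), and the exceptions Ndufv2, Ndufs8 and Uqcrc2 were lower by 0.21, 0.16 and 0.12. Cholesterol synthesis genes fell in 7 of 20 cases (7 adjusted over the list alone; camera adjusted p = 0.0203, and 0.812 with an estimated correlation). Examples were Nsdhl (1.55-fold, 1.48e-06) and Idi1 (1.68-fold). Ribosomal protein genes rose in 29 of 57 cases and fell in 8 (31 and 9 adjusted over the list alone; camera adjusted p = 9.72e-05, and 0.773 with an estimated correlation), Rpl24 rising 2.23-fold (11.05 ± 0.088 against 9.89 ± 0.14, 5.53e-11) and Rpl38 falling 1.75-fold (11.48 ± 0.05 against 12.29 ± 0.074, 1.32e-14). Cell cycle genes fell in 22 of 53 cases (23 adjusted over the list alone; camera adjusted p = 0.000623, and 0.812 with an estimated correlation). Among them were the mitotic genes Ube2c (1.75-fold, 0.000143) and Bub1 (1.79-fold), with the G1 regulators E2f1 and Ccnd1 as the exceptions (0.21 and 0.67). Small nucleolar RNAs rose in 22 of 41 cases (23 adjusted over the list alone; camera adjusted p = 2.97e-05, and 0.678 with an estimated correlation) and microRNA probe sets in 41 of 115 (41 adjusted over the list alone; camera adjusted p = 0.000285, and 0.725 with an estimated correlation). B cell markers fell in 7 of 22 cases (10 adjusted over the list alone). Cd79a was 1.86-fold lower (9.25 ± 0.18 against 10.14 ± 0.20, 0.000262), and Blnk was the exception (higher by 0.23 on the log2 scale). Camera did not call the list (adjusted p = 0.078). Blnk and the cholesterol synthesis list lost their calls without PBS replicate 1 or BG replicate 1 (adjusted p from 0.0537 to 0.196, each for at least 1 of these arrays).

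**Figure D4:**
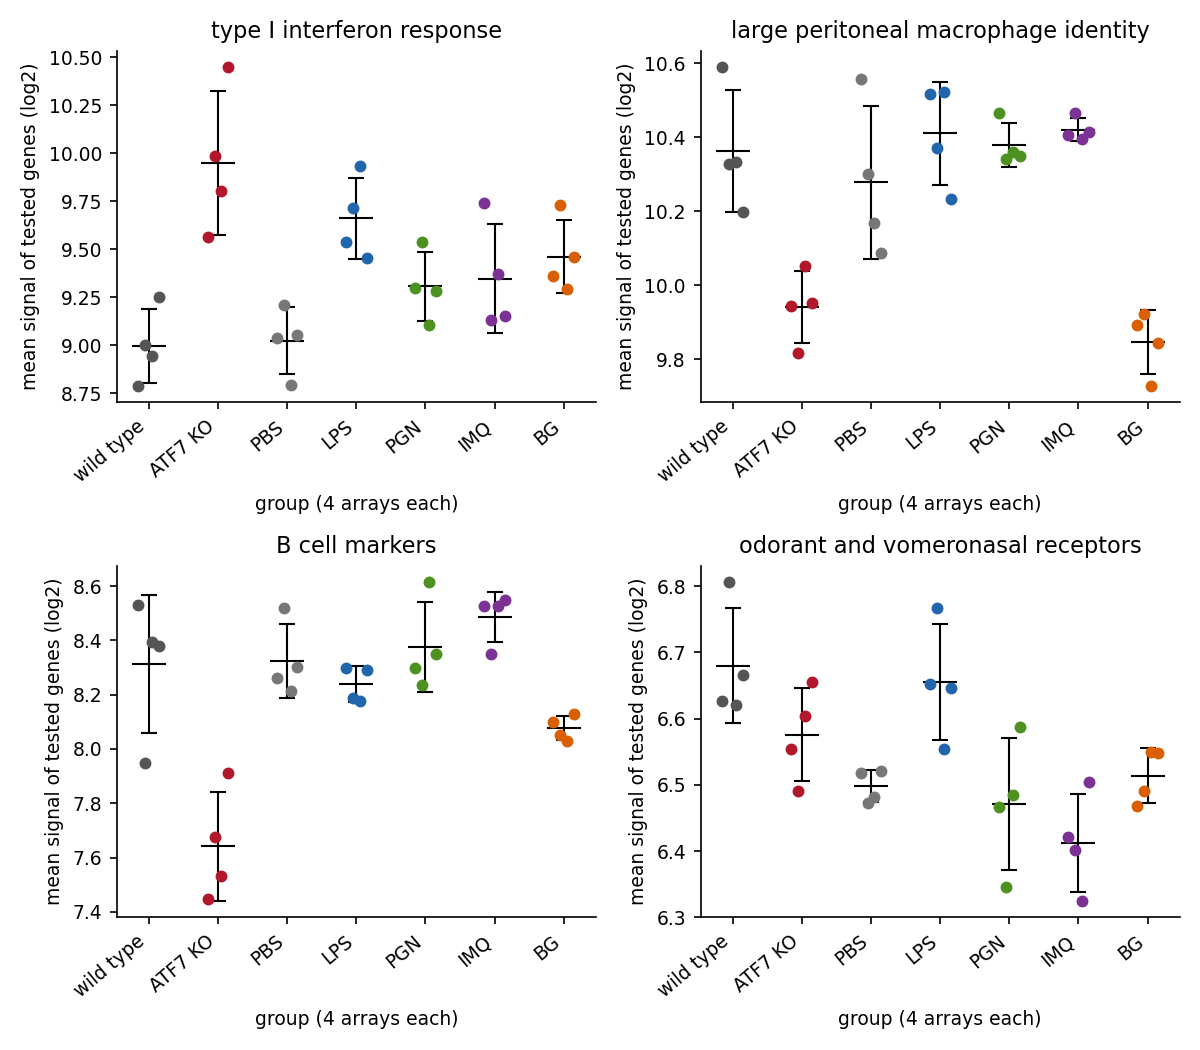
Mean log2 signal of the tested type I interferon-response genes, identity genes of large peritoneal macrophages, B cell markers and odorant and vomeronasal receptor genes on each array, by group; points are arrays and bars are group means with the SD. The interferon mean is 8.99 ± 0.19 in wild type, 9.95 ± 0.38 in the knockout, 9.02 ± 0.17 after PBS and 9.66 ± 0.21 after LPS, and the identity mean is 9.94 ± 0.097 in the knockout and 9.85 ± 0.086 after BG.

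The ligands were then compared with each other. Any difference among the 4 ligands and PBS was called for 7274 of 13512 genes (53.8%) by limma's F test. LPS against BG called 4719 genes (2254 higher after LPS and 2465 lower), LPS against IMQ 2590 (871 and 1719) and LPS against PGN 1632 (403 and 1229). The splits were 1037 and 1129 for LPS against IMQ and 569 and 951 for LPS against PGN after quantile normalisation, and 660 and 2008, and 239 and 1851, with centred arrays. Of 28 macrophage identity genes, 18 were higher after LPS than after BG (19 adjusted over the list alone; camera adjusted p = 1.39e-07, and 0.916 with an estimated correlation). Of 41 type I interferon genes, 7 were higher after LPS than after PGN (11 adjusted over the list alone; camera adjusted p = 4.94e-10, and 0.778 with an estimated correlation), 6 than after IMQ (6 adjusted over the list alone; camera adjusted p = 3.82e-07, and 0.752 with an estimated correlation) and 6 than after BG (3 adjusted over the list alone; camera adjusted p = 0.0309, and 0.948 with an estimated correlation). The count for LPS against PGN fell to 676 without LPS replicate 2, 815 without PGN replicate 2 and 1066 without LPS replicate 1, and that for LPS against IMQ to 1195 without LPS replicate 2, 1325 without IMQ replicate 3 and 1681 without IMQ replicate 2. With the background covariate the counts were 133 for LPS against PGN, 88 for LPS against IMQ and 4071 for LPS against BG.

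Correlations of the changes against PBS share the PBS arrays, which alone give correlation, so each is set beside 100 simulations of unchanged groups. Between PGN and IMQ, both with Tgm2, Vegfa and Hp among their largest rises, Pearson's r across genes was 0.808 against 0.499 simulated, the covariance exceeded the simulated one by 0.00935, and r averaged 0.479 with the PBS arrays split between the comparisons. For these, 343 genes were called in the same direction where independent lists would share 15.12. Between LPS and BG r was 0.422 against 0.499 simulated, the covariance excess 0.0128 and the split-control r 0.307, with 630 shared calls against 278.8. The remaining pairs also had an observed r below the simulated one, at 0.435 for LPS and PGN (0.498 simulated), 0.377 for LPS and IMQ (0.498), 0.476 for PGN and BG (0.498) and 0.369 for IMQ and BG (0.499). Their covariance excesses were 0.00513, 0.00468, 0.0102 and 0.00812, their split-control r 0.216, 0.179, 0.305 and 0.23, and their shared calls 66, 93, 307 and 413 where 25.86, 37.6, 109.6 and 159.6 were expected. In 1 low-numbered probe set without a gene name, chosen after its values were seen, the PGN and IMQ arrays also stood apart together, with a linear signal of 1847 ± 53.5 and 1934 ± 114 against 2908 ± 129 after PBS and group means from 2587 to 2923 elsewhere. The likeness of PGN and IMQ was not separated from joint handling of these arrays. Part of any excess may come from the shared controls, and genes are not independent replicates.

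The control groups also differed. PBS-injected mice against uninjected wild type, a comparison that holds the injection together with any difference between these sets of arrays, called 4415 of 13512 genes (32.7%), 2667 higher and 1748 lower (3916 and 934 with centred arrays), of which 81 by at least 1.5-fold. Hpgd rose 2.05-fold (8.54 ± 0.31 against 7.51 ± 0.26, limma adjusted p = 0.00131), Vsig4 1.84-fold (9.60 ± 0.30 against 8.72 ± 0.18, 0.000183) and Mrc1 1.76-fold (0.000343), and Park7, a redox-sensitive chaperone gene, fell 1.5-fold (1.38e-06). Lysosome and autophagy genes rose in 18 of 33 cases (20 adjusted over the list alone; camera adjusted p = 9.42e-05, and 0.651 with an estimated correlation). The exception was Becn1 (fell by 0.24). In limma 0 of 41 type I interferon genes passed (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; camera adjusted p = 0.906). Ribosomal protein genes fell in 21 of 57 cases (23 adjusted over the list alone; camera adjusted p = 1.32e-08, and 0.651 with an estimated correlation). The exception was Rpl7l1 (rose by 0.12). The count fell to 2783 without wild-type replicate 1 and 2752 without wild-type replicate 2, and to 1914 with the background covariate.

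Lists that follow background or other cells moved in this comparison too. Odorant and vomeronasal receptor genes fell in 33 of 110 cases (32 adjusted over the list alone; camera adjusted p = 3.73e-11, and 0.651 with an estimated correlation) and microRNA probe sets in 41 of 115 (44 adjusted over the list alone; camera adjusted p = 1.32e-08, and 0.651 with an estimated correlation), while small nucleolar RNAs rose in 19 of 41 (19 adjusted over the list alone; camera adjusted p = 9.42e-05, and 0.651 with an estimated correlation). Camera also called mesothelial and fibroblast markers, T and NK cell markers, cholesterol synthesis genes (these 3 lower) and cell cycle genes (higher), with adjusted p from 0.0125 to 0.0415 and, with an estimated correlation, from 0.651 to 0.88. Leaving out wild-type replicate 1 or 2 or PBS replicate 1, 2 or 3 ended the call of Rpl7l1 (adjusted p from 0.0634 to 0.119).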

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

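Tests chosen only after the result was seen were the genes near Atf7, the handling of arrays in sets, the reason why the interferon calls ended and the size of the interferon change with a background covariate or without 1 array. The background covariate itself was also chosen after seeing the data. The others were planned.

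Interferon-response genes were higher after LPS, with 32 of 41 called, in a group with a higher background. With the background as a covariate 0 of the 32 stayed called and with the B cell markers 31 of the 32 did, which argues against B cells as the source. The background covariate ended the calls while the median change stayed at 0.563 (median standard error 0.17) against 0.586 (0.158). The highest p that passed the adjusted threshold went from 0.00494 to 3.81e-05, with 12 genes passing in all, and 24 of the 32 were still under 0.00494. For these 24 the calls ended through the threshold. Without LPS replicate 2 it went to 1.34e-05, and 28 of the 32 were under 0.00494. Leaving out 1 array left between 0 (without LPS replicate 2) and 29 called members while the lowest median was 0.501, which argues against either as the source of the size of the change, but whether single genes pass depends on each. Background and a lasting response to LPS cannot be told apart for the calls of single genes, since the 4 LPS arrays have both.

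Identity genes of large peritoneal macrophages were lower in the knockout, 15 of 28, with the B cell markers lower in the same arrays. Variants carried along with the deleted gene cannot be told apart from its loss. Of the 15, 0% lay among the 115 tested genes nearest to Atf7, but only 1 of the 28 identity genes lies there at all, and a variant could act on genes elsewhere. Without any 1 array at least 14 stayed called. With the B cell markers as a covariate 8 of the 15 stayed called. The median went from -0.268 (median standard error 0.104) to -0.206 (0.169). Marker means did not overlap between knockout (up to 7.91) and wild type (from 7.95), so B cells and genotype were not separated. B cell genes kept signal after the wash of non-adherent cells, and 0 of the 22 is in another list. Of the most abundant, Cd79b (9.47 ± 0.40 against 10.62 ± 0.33) and Cd79a (8.82 ± 0.52 against 10.04 ± 0.38) were lower in the knockout. Blnk (9.92 ± 0.018 against 9.78 ± 0.20) and Cd72 (9.54 ± 0.48 against 9.70 ± 0.27) did not pass. Neither fell with Cd79a after BG.

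Arrays of BG-injected mice differed from PBS in many probe sets. Of 6617 low-numbered probe sets without a gene name, 23.3% differed between BG and PBS, which lies between the bounds set for and against handling of arrays in sets that follow the groups. Handling in sets cannot be told apart from an effect of BG, since the labels give no dates or sets. The same is open for PGN and IMQ, where a smaller share of low-numbered probe sets changed (4.16% and 4.17%). These were 275 and 276 of the 299 and 461 changed probe sets without a gene name. PGN and IMQ arrays also shared a low signal of 1 such probe set. With the background as a covariate 5798 genes passed against 5624, which argues against a background shift as a possible explanation.

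Some arrays lay far from the other 3 of their group. This concerned 5 of 142 sets of 4 values, where chance marks about 1 in 20. PGN replicate 1 had a mean of identity genes of 10.47 (others 10.34 to 10.36) and an Arg2 level of 10.32 (others 10 to 10.06), and PGN replicate 2 a Tgm2 level of 10.05 (others 9.83 to 9.86). IMQ replicate 2 had a mean of B cell markers of 8.35 (others 8.53 to 8.55), and knockout replicate 4 an Mrc1 level of 8.25 (others 8.56 to 8.58).

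Effects differed between groups by direct tests, for 1632 genes between LPS and PGN, 2590 between LPS and IMQ, 4719 between LPS and BG and 3958 between the knockout effect and the LPS effect. Probe sets without a gene name, which no comparison of genes used, also changed, 556 of 12146 in the knockout, 177 after LPS, 299 after PGN, 461 after IMQ, 2778 after BG and 1096 in PBS against wild type.

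Other splits of the same arrays were fitted to ask whether chance can be excluded. Of the 35 splits of 8 arrays only the real 1 gave as many genes in each of 9 comparisons. That is the smallest share that 35 splits can give, and it was not adjusted over the 9 comparisons. It makes chance less likely without excluding it, and the margin was smallest after LPS. The real count and the highest other were 3830 and 945 in the knockout, 1335 and 1006 after LPS, 528 and 4 after PGN, 769 and 0 after IMQ, 5624 and 67 after BG, and 4415 and 1303 in PBS against wild type. They were 1632 and 2 for LPS against PGN, 2590 and 54 for LPS against IMQ, and 4719 and 3 for LPS against BG. For the F test only the real 1 of 100 splits gave as many as 7274 genes (highest other 271). For the difference between the knockout and LPS effects only the real 1 of 100 splits gave as many as 3958 genes. The highest other gave 3503, and other splits kept part of the real contrasts, so chance was not excluded there either. For the correlation between the knockout and LPS effects, 95 of 100 splits gave a value as large as 0.0166 (highest other 0.598), so chance cannot be excluded.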

How the results depend on the processing

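The background covariate, the other Atf7 probe set and the comparison of PGN with IMQ were chosen after seeing the data. Where no reason is given, the cause was not tested.

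A minimum of 1.5-fold left 417 genes in the knockout, 63 after LPS, 21 after PGN, 28 after IMQ, 312 after BG, 81 in PBS against wild type, 55, 52 and 275 for LPS against PGN, IMQ and BG, 484 for the difference between the knockout and LPS effects and 362 for any ligand, by construction. An adjusted p under 0.1 gave 3037 genes after LPS, 897 after PGN, 1363 after IMQ, 2671 for LPS against PGN and 3917 for LPS against IMQ, also by construction. Fitting only the groups compared, which leaves fewer arrays to estimate the spread, gave 2409 genes in the knockout, 508 after LPS, 272 after PGN and 2066 in PBS against wild type, and fitting only the 5 injected groups gave 2282 after LPS. Array weights gave 2018 after LPS, 1419 after PGN, 1699 after IMQ and 2728 in PBS against wild type. A stricter filter gave 877 and quantile normalisation 863 after LPS.

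With the B cell markers as a covariate 1423 genes passed in the knockout, 1635 for LPS against IMQ and 1912 for the difference between effects. With the background as a covariate 12 passed after LPS, 1914 in PBS against wild type, 133 and 88 for LPS against PGN and IMQ and 1531 for the difference between effects. The LPS calls were thus not separated from the array background. The B cell covariate reversed Ccr7 (0.098), Chaf1a (0.000122) and Phgdh (0.011) in the knockout and, by construction, the B cell list after IMQ (-0.014). Camera with an estimated correlation called 0 of 180 lists (8 in the knockout and 3 after LPS at an unadjusted p under 0.05), and fry called 50, 36 of them with camera. The correlation of the knockout and LPS effects was -0.181 by Spearman's rho. The median correlation between ligand effects was 0.268 with the PBS arrays split, against 0.428.

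Leaving out 1 array at a time gave 2942 to 3991 genes in the knockout, 4 to 1558 after LPS, 283 to 483 after PGN, 400 to 758 after IMQ, 4837 to 5277 after BG and 2752 to 5306 in PBS against wild type. For LPS against PGN, IMQ and BG the ranges were 676 to 1805, 1195 to 2824 and 4076 to 4610, for the difference between effects 2859 to 4998, for any ligand 6351 to 7562 and for called lists 58 to 67. The correlation of the knockout and LPS effects ranged from -0.0816 to 0.0953 and the change of Atf7 from -0.477 to -0.424.

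With a replicate block the counts were 3845 in the knockout, 1438 after LPS, 508 after PGN, 765 after IMQ, 5667 after BG, 4415 in PBS against wild type, 1674, 2619 and 4781 for LPS against PGN, IMQ and BG, 3980 for the difference between effects and 7286 for any ligand, and 65 lists were called. In no comparison did all 4 pairs of same-numbered arrays correlate above 0.1, but 3 of 4 did for PGN and PBS (0.258, 0.187 and 0.112) and 2 of 4 for LPS and PBS (0.312 and 0.446), BG and PBS, and PBS and wild type.

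Every total of genes, though not every count of higher or lower genes, stayed within 1.5 times of the reported one with centred arrays, with no filter, with the mean of a gene's probe sets and with the fit without the intensity trend. Without 1 array, 4789 tests of named genes kept their status, called or not, and 625 lost the call. The background covariate ended 137 calls, the B cell covariate 76, fitting only the groups compared 111 and centred arrays 49. With signal over background as the measure of depth, genes under the floor of 80.04 were not tested, against array medians of 107 to 115, and folds of genes close to the floor are compressed.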

Other observations

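Tests chosen after the result was seen in this part are the overlap of identity genes and the correlation of interferon genes. The other lists were tested and camera called none of them in the 5 main comparisons. In the knockout, MHC class II genes went both ways, with Cd40, Ifi30 and Ctss higher by 0.57, 0.19 and 0.14 on the log2 scale and H2-Eb2, H2-Ob, H2-Aa and H2-Eb1 lower by 1.05, 0.73, 0.38 and 0.29, genes chosen after their values were seen. The calls of Ctss and H2-Eb1 ended without wild-type replicate 1 or 2 or knockout replicate 1, 2, 3 or 4 (adjusted p from 0.0615 to 0.105), each for at least 1 of these arrays. Camera's adjusted p over the comparisons ran from 0.242 to 0.876 for MHC class II, from 0.0912 to 0.931 for complement, from 0.575 to 0.996 for reactive oxygen and nitrogen production, from 0.163 to 0.703 for glycolysis, from 0.339 to 0.896 for lipid efflux and LXR targets, from 0.365 to 0.929 for the ATF/CREB and AP-1 family and stress kinases, and from 0.431 to 0.802 for H3K9 methylation and heterochromatin. It ran from 0.259 to 0.752 for neutrophil, from 0.28 to 0.985 for erythroid and platelet, and from 0.0631 to 0.476 for sex-linked genes, and from 0.476 to 0.752 for genes near Atf7. In the H3K9 list of the knockout, Atf7ip, whose product binds ATF7, fell by 0.17. Dnmt1, which rose by 0.21, Cbx1, Dnmt3a and Chaf1a passed as well but not without 1 array (wild-type replicate 1, 2 or 3 or knockout replicate 1, 2 or 3, adjusted p from 0.0504 to 0.156), and Chaf1a turned to 0.000122 with the B cell markers as a covariate.

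Of 28 identity genes 15 fell in the knockout and 17 after BG, and 12 fell in both where 9.11 were expected (Fisher's exact p = 0.031, testing for excess only, not both directions). Loss of ATF7 and BG might act on the same part of the identity programme, a hypothesis found and tested on the same data, and Atf7 itself was lower after BG. With the background or B cell markers as a covariate 17 identity genes were lower after BG. With the B cell markers 8 rather than 15 were in the knockout, so at most 8 could then be shared.

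The interferon genes that rose most in the knockout were also those that rose most after LPS (Pearson's r = 0.678 over 41 genes). A candidate explanation is that both states raise the same interferon signal, which was not separated from a shared sensitivity of these genes to any such signal. Across all genes r was 0.0166 and over the 416 called in both 0.505, and the direct comparison of their effects called 3958 genes.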
